A study of Mus musculus with 6 samples.

How the data were processed

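Bone marrow cells of wild-type and Mof heterozygous mice were sorted by flow cytometry into 6 populations, 15 cells per sort, flash frozen and made into libraries with CEL-Seq2, per the labels' protocols. The gates, per the series design, were Lin-negative Sca-1-positive cKit-positive (LSK) CD34-negative Flt3-negative CD48-negative CD150-positive for HSC. MPP2, MPP3 and MPP4 were CD34-positive CD48-positive LSK cells, told apart by CD150 (positive in MPP2) and Flt3 (positive in MPP4). CMP and MEP were Lin-negative Sca-1-negative cKit-positive IL7r-negative cells, with CD34 and low CD16/32 in CMP and neither in MEP. The labels list 6 pools, 3 per genotype (HSC, the MPP populations, and CMP with MEP). The 12 tables hold 1 population and genotype each, with 3 libraries per table and 36 in all. Genotype and pool cannot be told apart in any population, and no fit with pool as a term can be had. Column numbers are running barcodes that no 2 groups share.

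Reads were aligned to mm10 with BWA 0.6.2-r126, per the submitters' processing notes. How molecular identifiers were collapsed, which counter was used and which gene annotation was used are not given in the sources used here. The deposited values are a signal per gene: counts that the authors divided by 1 size factor per library. This was read from the values, of which 100% are whole multiples of the library's step (within 0.01 counts), so whole counts were recovered. Outside MEP, the size factors equal DESeq2's median-of-ratios factors over the 6 libraries of each population, with spike-in transcripts included. In MEP, factors from genes alone differed from the deposited ones by up to 0.396%. Whether spike-ins were used there could not be checked, because the heterozygous MEP table lacks them. Genotypes of 1 population therefore share a scale, and populations do not. The tables hold 23538 genes, and 55 symbols stand on more than 1 line and were kept apart by their identifier. In 10 tables, 92 spike-in transcripts are named; they were kept out of library totals and tests.

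In the wild-type MEP table the names of the spike-ins are missing while their values are present, so that after the first 6842 genes the names of 16696 genes stand 92 lines too early and the last 92 lines have no name. The values were put back in the order of the other tables. The rank correlation of the mean profile with wild-type CMP (across genes, which are not independent replicates) was 0.136 with the names as deposited and 0.906 in that order. The heterozygous MEP table has no spike-in lines and needed no change.

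The design was written for counts, with limma on log values to be used if the files held normalised values, which they did. The main test was limma (version 3.58.1, R 4.3.3) on log2(value + 1), with an intensity trend in the prior variance, over all 36 libraries, with 1 coefficient per population and genotype. Genes with a mean value of at least 1 were tested (6444 genes), and p-values were adjusted by Benjamini-Hochberg at a false discovery rate of 0.05. Contrasts were heterozygous minus wild type in each population, their average over the 6 populations, and the interaction of genotype with population. The wild-type populations were each compared with the mean of the other 5, on recovered counts rescaled to a common total of 41227. Fold changes on the log2(value + 1) scale can understate the change of low genes. Where libraries of 1 group hold 0 counts, they can exceed the ratio of pooled counts, as for Ctla2a in MPP3 (13.3-fold against 2.88). The recovered counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, its default filter on low counts, 1633 genes, common dispersion 0.113), an alternative chosen after seeing the data; it called 31 genes on average against 5 by limma. Kat8 was tested without the filter, and by permutation tests on the same log2 values (100000 resamples), which were chosen after seeing the data. Ratios of pooled counts carry exact 95% intervals, and a count of 0 was bounded by 3 counts over the group.

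Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The lists covered the MSL and NSL complexes, other lysine acetyltransferases and deacetylases, HSC, megakaryocyte, erythroid, myeloid and lymphoid priming genes, blood transcription factors, surface proteins of the sort, G1/S, G2/M and quiescence genes, p53 targets, interferon response and immediate early genes, glycolysis, respiratory chain and ribosomal protein genes, and markers of mature B cells, T and NK cells, neutrophils, macrophages and dendritic cells, mast cells, stroma and sex. Of 26 lists, 25 had tested members. Lists overlap in part (Klf6 and Egr1 are both immediate early and quiescence genes). Of the 13 mature neutrophil and 13 mature B cell genes, 10 and 9 passed the filter in these libraries, and Vpreb3 of the B cell list is also made by B cell precursors. Samples, lists, contrasts and the rule for naming genes were fixed before the data were examined. So were the alternatives, except those marked as chosen after seeing the data.

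Kat8 was always named. For the average, genes past the threshold were named, up to 10 in each direction. They needed the sign of the average in at least 5 of 6 populations and mean CPM at or above the median of tested genes (61.4). For each population, up to 5 genes past the threshold were named in each direction. Their replicates did not overlap between genotypes, and their mean CPM in that population reached the median of tested genes in that population. Also named were the 5 smallest interaction p past the threshold, and for wild-type populations the 5 largest increases. From each list up to 4 members were named, those past the threshold or otherwise those with the highest mean CPM, and all members of the sort and MSL and NSL lists may be named. Some list members that this rule takes are not reported here. Other named genes are marked as chosen after their values were seen, except where a list's members past the threshold over the list alone are given. Coordinates are of mm10 (GRCm38), from the GENCODE vM21 and RefSeq GRCm38.p6 annotations. Reads of pseudogenes and gene copies, of overlapping genes and of antisense pairs (Rps15a-ps6, Gm6251, Gm10548, Erdr1, Mir682, and Exosc2 with Gm13427) may be shared with other genes, and their counts are uncertain.

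Total counts of 1577 to 123765 per library set the precision: 1 count was 634 CPM in the shallowest heterozygous HSC library and 8.08 CPM in heterozygous CMP replicate 3. The procedures were tested on counts simulated from the real means and totals with 200 changed genes. For the average, limma (6446 genes) recovered 26.7% of 2-fold, 90.9% of 4-fold and 100% of 8-fold changes, with 13 false calls, 11 of them higher. Within a population it recovered 10.7% of 8-fold changes in HSC, 39.3% in MPP2, 57.1% in MPP3, 58.9% in MPP4, 66.1% in CMP and 64.3% in MEP. In simulated MPP3 there were 29 false calls, all higher, against 3 by edgeR (1855 genes), and in MEP 13 by limma. For wild-type MPP3 and MPP2 against the others, limma made 256 and 55 false calls in the simulation. The set test passed a list shifted 2-fold in all 7 contrasts and at most 1 unshifted list per contrast (6435 genes). Simulated genes varied independently of each other, so that number does not cover lists whose members vary together. Other groupings of the real HSC libraries passed up to 13 lists.

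Alternatives were DESeq2 1.42.0, edgeR with RLE or total scaling, no filter and a stricter filter, a pseudocount of 0.1, the 2 tables of 1 population alone, sums over replicates, leaving out ribosomal and sex-linked genes, leaving out the 6 shallow libraries, and leaving out each library in turn. Chosen after seeing the data were the edgeR test with TMM scaling, the same without the 6 shallow libraries, camera on recovered counts, the gene lists without the shallow libraries, and the wild-type MEP names as deposited. So were counts per spike-in count, with and without the shallow HSC library, and the genes near Kat8, with and without Tspan32 and Ifitm1. Tables were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9.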

Results

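The data describe how loss of 1 copy of Mof (gene symbol Kat8), the lysine acetyltransferase that places acetyl groups on lysine 16 of histone H4, goes with the transcripts of early blood-forming cells of the mouse. Sorted bone marrow cells of 6 populations were profiled by CEL-Seq2, a method that tags and counts the 3' ends of messenger RNA, from 15 cells per sort. The populations were haematopoietic stem cells (HSC), the multipotent progenitors MPP2, MPP3 and MPP4, common myeloid progenitors (CMP) and megakaryocyte-erythroid progenitors (MEP). Each population was given as 3 wild-type and 3 Mof heterozygous libraries, 36 libraries in all. The libraries were sequenced in 6 pools, 1 per genotype for the HSC, for the 3 MPP populations and for the CMP with the MEP. Each genotype comparison is therefore also a comparison of 2 pools. Nothing in the labels says that the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

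Total counts ran from 1577 to 123765 per library, with a median of 41227, and 743 to 9359 genes were detected. Depth differed between the genotypes. The wild-type libraries of MPP2 and MPP3 averaged 11322 and 10302 counts, against 33470 and 70090 in the heterozygous libraries (n = 3 each). Mean totals in wild-type and heterozygous libraries were 31583 and 24972 in HSC, 31492 and 71775 in MPP4, 69288 and 91504 in CMP, and 64716 and 79991 in MEP. In 6 libraries the total was 12339 or lower. These were the 3 wild-type MPP2 libraries (10331, 12339 and 11295 counts), wild-type MPP3 replicates 1 and 2 (7304 and 2764) and heterozygous HSC replicate 2 (1577). They are called the 6 shallow libraries from here on. Levels are also given as CPM, a gene's count scaled to the same library total throughout. A single count was worth 634 CPM in heterozygous HSC replicate 2 and 8.08 CPM in heterozygous CMP replicate 3. Intervals and floors below cover counting error only.

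**Figure D1:**
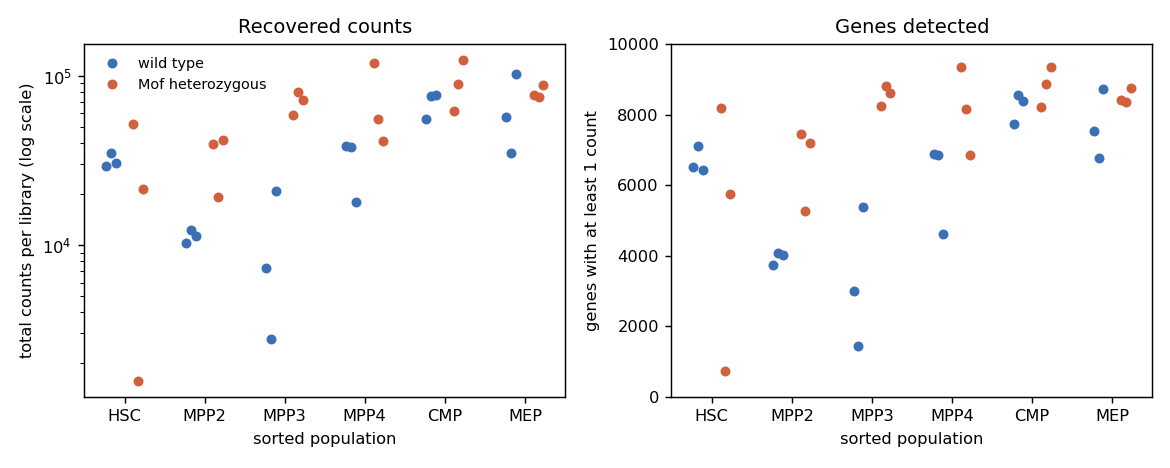
Total counts (log axis) and number of genes detected in each of the 36 libraries, by population and genotype. Totals run from 1577 to 123765, and the wild-type MPP2 and MPP3 libraries are shallower than the heterozygous libraries of the same populations on average.

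Kat8 itself was too sparsely counted to show a difference of genotype. The 18 wild-type libraries held 12 Kat8 counts in 656112, or 18.3 CPM (exact Poisson 95% interval 9.45 to 31.9). The 18 heterozygous libraries held 11 counts in 1115410, or 9.86 CPM (4.92 to 17.6). Both pooled levels also reflect the mix of populations among the counts, which differed between the genotypes. At least 1 count was present in 7 wild-type and 9 heterozygous libraries. Averaged over populations, Kat8 differed by -0.08 log2 (SE 0.21, 95% interval -0.51 to 0.35; two-sided permutation test within populations, 100000 resamples, p = 0.702), which became 0.0502 when wild-type CMP replicate 2 was left out. The log2(value + 1) scale compresses counts this low, so that interval does not bound the relative loss of Kat8 RNA. Over 9 alternatives the difference ran from -0.72 (DESeq2) to 0.0158 (pseudocount of 0.1), none past the threshold, and a loss in proportion to 1 missing copy is not excluded. The differences were -0.33 in HSC, 0.19 in MPP2, -0.07 in MPP3, -0.47 in MPP4, 0.03 in CMP and 0.17 in MEP, and limma gave an adjusted p = 0.961 for the average over these 7 tests (Benjamini-Hochberg). Kat8 did not differ detectably between wild-type populations (permutation test on the sum of squares between populations, 100000 resamples, p = 0.699). Kat8 lies at 127912516 to 127925837 on the plus strand of chromosome 7 (mm10) and overlaps Prss8. The labels do not say which part of the gene the allele lacks, so 3' tags need not check the genotype.

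Wild-type CMP, MEP and MPP4 differed from the other populations in transcripts of blood lineages. The gene lists that rose within each population were of different lineages. Myeloid, megakaryocyte and mast cell genes rose in CMP, and erythroid and mature neutrophil genes in MEP. In MPP4, lymphoid priming, mature B cell, and macrophage and dendritic cell genes rose. Chance could not be excluded for the number of genes called in each population, as described below. CMP were rich in Mpo, the myeloperoxidase of granulocyte precursors (1615 ± 185 CPM, SD, n = 3, against 138 CPM in the other populations), and MEP in Car1, an erythroid carbonic anhydrase (1702 ± 316 against 105 CPM). Outside their own population, Mpo reached 918 CPM (MEP replicate 3) and Car1 576 CPM (CMP replicate 3), below the lowest CMP and MEP library. MPP4 were rich in Vpreb1 (811 ± 323 against 99.2 CPM) and Igll1 (462 ± 15.9 against 66.0 CPM), which form the surrogate light chain of the early B lineage. HSC replicate 3 held 458 CPM of Vpreb1, above the 443 CPM of MPP4 replicate 3, and 425 CPM of Igll1, below every MPP4 library. HSC held 287 ± 27.3 CPM of Gimap6, a GTPase of immune cells, against 55.7 CPM in the other populations. Single libraries outside HSC reached that level, with 277 CPM of Gimap6 in MPP4 replicate 3 and 257 CPM in MEP replicate 2. Each population was compared with the mean of the other 5, on recovered counts rescaled to a common total of 41227. The limma F test called 245 of 6501 genes across populations.

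**Figure D2:**
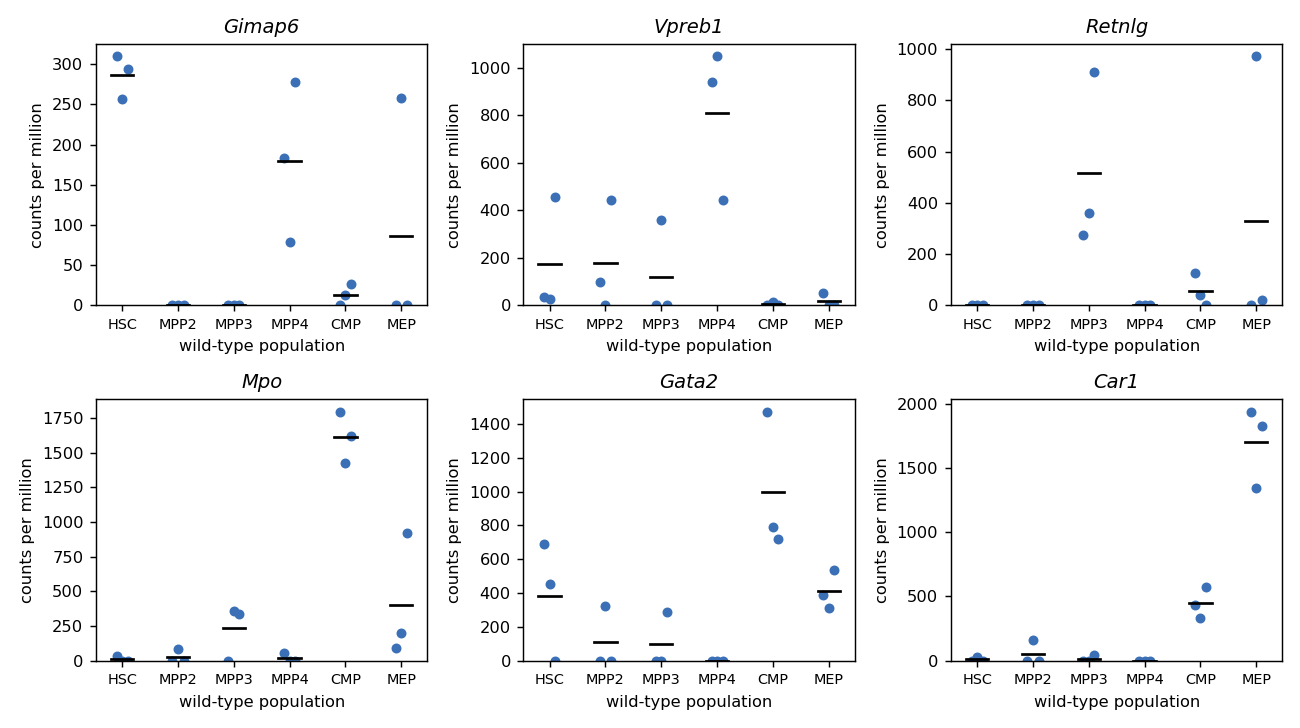
CPM of Gimap6, Vpreb1, Retnlg, Mpo, Gata2 and Car1 in each wild-type library, with the mean of each population as a line. Mpo averages 1615 CPM in CMP and Car1 averages 1702 CPM in MEP.

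In CMP, 9 genes rose and 2 fell (limma, Benjamini-Hochberg adjusted p under 0.05). Mpo rose by 4.496 log2 (SE 0.64, adjusted p = 1.50e-05). The neutrophil granule proteases Ctsg (3.36, adjusted p = 2.88e-04) and Elane (2.89, adjusted p = 0.00556; 256 CPM, below the 781 CPM of wild-type MEP replicate 3), the stem and mast cell transcription factor Gata2 (3.38, adjusted p = 0.0136; 995 ± 415 CPM) and the platelet factor Pf4 (3.16, adjusted p = 0.0136) rose with it. As groups, the myeloid genes (median 1.30, camera adjusted p = 8.54e-10) rose and the mature B cell genes (median -2.06, adjusted p = 5.39e-21) fell. Both calls held with an estimated correlation (adjusted p = 0.00799 and 0.00264). The count test, edgeR's quasi-likelihood test on recovered counts, called 87 genes (67 higher). Leaving out wild-type CMP replicate 1, 2 or 3 gave 3, 2 or 4 genes.

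In MEP, 4 genes rose and 1 fell (limma). Car1 rose by 4.91 log2 (SE 0.56, adjusted p = 1.44e-08), the metal-binding Mt1 by 3.09 (adjusted p = 4.73e-05), the noncoding Gm15915, which lies antisense within Ntn4, by 2.69 (adjusted p = 2.17e-04) and the sodium pump subunit Atp1b2 by 2.55 (adjusted p = 5.13e-04). The erythroid genes rose as a group (median 0.65, camera adjusted p = 0.00977; adjusted p = 0.627 with an estimated correlation), and the genes of the sort's surface proteins fell (median -0.76, adjusted p = 7.43e-04; adjusted p = 0.0636 with an estimated correlation). Mature neutrophil genes also rose (median 1.12, adjusted p = 0.00252; adjusted p = 0.514 with an estimated correlation). Their summed level was 33261 and 11458 CPM in wild-type MEP replicates 2 and 3 and 652 CPM in replicate 1. The count test (edgeR) called 113 genes (89 higher), and limma called 8 without wild-type MPP3 replicate 3.

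In MPP4, 6 genes rose and 2 fell (limma). Besides Vpreb1 (3.71 log2, SE 0.69, adjusted p = 0.00318) and Igll1 (3.42, adjusted p = 0.00318), these included the lymphoid transcription factor Lef1 (2.77), the heparan sulphate proteoglycan Sdc4 (2.43), both at adjusted p = 0.00914, and Bfsp2 (2.23, adjusted p = 0.0342). Lymphoid priming genes (median 1.37, camera adjusted p = 1.27e-08) and mature B cell genes (median 1.68, adjusted p = 5.22e-11) rose as groups, each with adjusted p = 0.0342 with an estimated correlation. Macrophage and dendritic cell genes rose as well (median 1.27, camera adjusted p = 0.00466, adjusted p = 0.429 with an estimated correlation). The count test called 22 genes (19 higher). Leaving out wild-type MPP4 replicate 1, 2 or 3 gave 1, 1 or 5 genes.

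In HSC, 3 genes rose and 0 fell by limma, with 438 at an unadjusted p under 0.05 and 10 called by the count test. Gimap6 rose by 2.74 log2 (SE 0.60), the lymphotoxin gene Ltb by 2.61 and the cytokine-signalling inhibitor Cish by 2.22 (adjusted p = 0.0492 for each). The list of HSC genes rose (median 1.42, camera adjusted p = 8.12e-07; adjusted p = 0.0856 with an estimated correlation). Myeloid genes (median -1.06, adjusted p = 2.07e-12) and mature neutrophil genes (median -2.43, adjusted p = 2.07e-12) fell, with adjusted p = 0.00606 and 0.0455 with an estimated correlation. The 3 calls were fragile: 0 genes passed without wild-type HSC replicate 1 or 2, and 9 passed without replicate 3. In 15 of the 18 fits that left out 1 library the number of called genes moved by over 1.5 times.

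The wild-type MPP2 and MPP3 comparisons rest on shallow libraries. In MPP2, limma called 79 genes (29 higher, 50 lower) against 4 (2 higher, 2 lower) by the count test with TMM scaling and 36 (32 higher, 4 lower) with RLE scaling. The genes that rose most were the pre-B gene Vpreb3 (3.73 log2, SE 0.79, adjusted p = 0.00903, 2054 ± 627 against 424 CPM), Spib (3.69), Fcrla (3.35) and Sbk1 (2.77), each with adjusted p = 0.00674, and Irf8 (2.78, adjusted p = 0.0446). Except for Vpreb3, single libraries of other populations exceeded the lowest MPP2 library. Irf8 was 1095 CPM in MPP3 replicate 1 against 729 CPM in MPP2 replicate 2. Spib was 548 CPM in MPP3 replicate 1 against 443 CPM in MPP2 replicate 3. Mature B cell genes rose as a group (median 1.54, camera adjusted p = 3.49e-06, adjusted p = 0.491 with an estimated correlation). Macrophage and dendritic cell genes rose too (median 1.62, camera adjusted p = 0.00913, adjusted p = 0.837 with an estimated correlation). Leaving out wild-type MPP2 replicate 1 gave 23 genes, and leaving out wild-type MPP3 replicate 1 gave 188.

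In wild-type MPP3, mature neutrophil genes were high against the mean of the other populations. Their mean summed level was higher still in wild-type MEP (15123.5 against 12988 CPM). Retnlg, a neutrophil protein of the resistin family (3.61 log2, SE 0.61, adjusted p = 6.56e-04; 516 ± 346 against 77.1 CPM), the neutrophil calcium-binding proteins S100a8 (3.93, SE 1.17) and S100a9 (3.91), both at adjusted p = 0.0413 by limma, the chemokine Ccl4 (2.95, adjusted p = 0.00267) and Igsf6 (2.65, adjusted p = 0.00563) rose. The Igsf6 difference rested on 5 counts in MPP3. Retnlg did not pass the count test (edgeR adjusted p = 0.224), and wild-type MEP replicate 2 held more of it (972 CPM) than any MPP3 library (274 to 912 CPM). S100a8 and S100a9 averaged 3578 and 5050.1 CPM against 2220.4 and 2312 CPM in the other populations and did not pass the count test (edgeR adjusted p = 0.634 and 0.554); S100a8 was higher still in wild-type MPP4 replicate 3 (12029 CPM) and MEP replicate 2 (9773 CPM). Mature neutrophil genes rose as a group (median 2.35, camera adjusted p = 6.35e-10; adjusted p = 0.190 with an estimated correlation), as did immediate early genes (median 0.86, adjusted p = 5.82e-06; adjusted p = 0.238 with an estimated correlation). Macrophage and dendritic cell genes did not pass (median 0.41, camera adjusted p = 0.753), and 0 of them rose and 2 fell over all genes. Limma called 308 genes (55 higher, 253 lower) and the count test 1 (higher). The median of all genes was -0.54, and the limma count was 4 without wild-type MPP3 replicate 2 and 987 without replicate 3.

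Averaged over the 6 populations, heterozygous libraries held more RNA of Erdr1, an erythroid differentiation regulator, and of Exosc2, a subunit of the RNA exosome, and less of the immediate early transcription factor Klf6 and of the cell-cycle transcription factor E2f2. Erdr1 had the largest difference: 43 counts in wild-type and 729 in heterozygous libraries, or 65.5 against 654 CPM, a ratio of 9.97 (7.33 to 13.9). Exosc2 had 130 and 283 counts, or 198 against 254 CPM over the pooled libraries, a ratio of 1.28 (1.04 to 1.59), which is below the 2.29-fold of the mean log2 difference. Klf6 went from 440 to 229 CPM over the pooled libraries and E2f2 from 169 to 72.6 CPM. Pooling weighs each population by its counts, and that mix differed between the genotypes. MPP3 held 30907 of 656112 wild-type counts and 210269 of 1115410 heterozygous counts. These pooled levels, ratios and intervals therefore mix population with genotype. The mean log2 difference weighs the 6 populations equally, and what sets the 2 Exosc2 values apart was not tested. For low genes the log2(value + 1) scale can give a smaller change than pooled counts, or a larger one. On that scale Erdr1 rose by 2.80 (SE 0.27, adjusted p = 6.72e-11) with a positive difference in 6 of 6 populations. Exosc2 rose by 1.20 (SE 0.23, adjusted p = 0.00657; 5 of 6), Klf6 fell by 1.38 (SE 0.24, adjusted p = 0.00161; 5 of 6) and E2f2 fell by 1.32 (SE 0.30, adjusted p = 0.0485; 6 of 6), all by limma with Benjamini-Hochberg adjustment. The fifth called gene, the tetraspanin Tspan32, rose by 1.11 (SE 0.22, adjusted p = 0.0118; 23 against 100 counts; 6 of 6). It lies outside the naming rule and was chosen after its values were seen.

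Limma called 5 of 6444 genes (3 higher, 2 lower) and the count test 31 of 1633 (23 higher, 8 lower; 15 higher and 10 lower with RLE scaling, 33 and 20 by DESeq2), with 4 genes called by both. Without the 6 shallow libraries, which leaves 5 populations in the average (MPP2 drops out) and 1 wild-type MPP3 library, Erdr1 (3.03, adjusted p = 1.36e-10) and Klf6 (-1.66, adjusted p = 5.02e-05) were still called, and Exosc2 (0.74, adjusted p = 0.305), E2f2 (-1.02, adjusted p = 0.370) and Tspan32 (1.18, adjusted p = 0.101) were not. Leaving out 1 library ended the E2f2 call in 26 of 36 fits, and gave 43 genes without heterozygous HSC replicate 2, 16 without wild-type MPP3 replicate 3 and 8 without wild-type MPP2 replicate 3. In mm10, Exosc2 lies at 31670715 to 31681349 on chromosome 2 and overlaps the antisense gene Gm13427, Klf6 at 5861482 to 5870394 on chromosome 13, E2f2 at 136172394 to 136196057 on chromosome 4 and Tspan32 at 143005046 to 143019644 on chromosome 7. Erdr1 is given on chromosome Y in the tables, while the RefSeq annotation places it at 170010526 to 170018797 on chromosome X as a transcribed pseudogene overlapping Gm21887, so its reads are uncertain in origin. The median difference of all genes was 0.12 on the deposited scale and 0.17, 0.07 and 0.09 with TMM, RLE and total scaling.

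**Figure D3:**
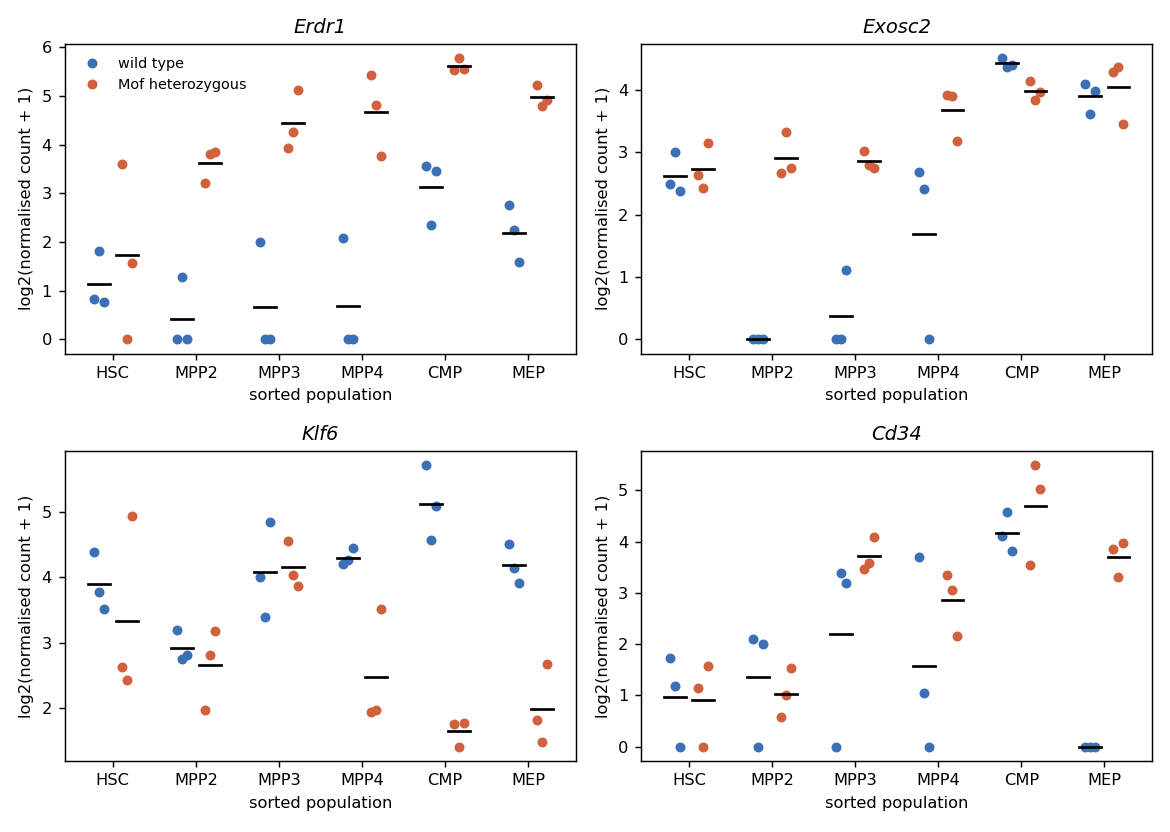
Log2(normalised count + 1) of Erdr1, Exosc2, Klf6 and Cd34 in each library, by population and genotype, with group means as lines. Klf6 is lower in all heterozygous CMP libraries than in any wild-type CMP library, and Cd34 has 0 counts in wild-type MEP.

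Of 25 gene lists, 7 differed on average by camera with a preset correlation of 0.01, and 0 held with an estimated correlation. The list of HSC genes was higher (median 0.59, adjusted p = 1.64e-04; adjusted p = 0.293 with an estimated correlation), with 10 of 12 members higher and 5 rising when adjusted over the list alone, against 0 over all genes. Its members included the interferon-induced membrane proteins Ifitm1 (1.27, SE 0.29) and Ifitm3 (1.03, SE 0.29) and the Tie2 ligand Angpt1 (0.82, SE 0.31). Immediate early genes were lower (median -0.48, adjusted p = 8.95e-10; adjusted p = 0.0905 with an estimated correlation). Of these, 15 of 18 were lower and 4 fell when adjusted over the list alone (Klf6, Jund -0.97, Fos -1.05 and Hspa1b -0.77), with Klf6 over all genes. Jun differed by -0.56 (SE 0.27).

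Genes of mature blood cells were lower in the heterozygous libraries. Mature neutrophil genes had a median of -1.15 (adjusted p = 1.49e-12; adjusted p = 0.0727 with an estimated correlation). Of its members, 9 of 10 were lower and 9 fell when adjusted over the list alone, against 0 over all genes, among them the calcium-binding S100a9 (-2.33, SE 0.59) and S100a8 (-1.86, SE 0.60) and the granule genes Camp (-1.72, SE 0.52) and Ngp (-1.35, SE 0.52). Mature B cell genes had a median of -0.82 (adjusted p = 1.19e-09; adjusted p = 0.0727 with an estimated correlation). Of its members, 9 of 9 were lower and 5 fell when adjusted over the list alone, against 0 over all genes (Vpreb3 -1.16, Cd79b -0.84, Cd79a -0.52 among the members). The B cell median was -0.28 without the 6 shallow libraries. Macrophage and dendritic cell genes had a median of -0.51 (adjusted p = 0.00298; adjusted p = 0.424 with an estimated correlation; Cd74 -0.67, H2-Aa -0.80, H2-Ab1 -0.51, Ccr2 0.14), with adjusted p = 0.0782 without wild-type MEP replicate 2 and 0.610 without the shallow libraries. The summed level of the neutrophil list varied widely within wild-type groups, from 209 to 33370 CPM in MPP4, 266 to 18778 in MPP2 and 652 to 33261 in MEP, and reached 28120 CPM in heterozygous MEP replicate 3.

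**Figure D4:**
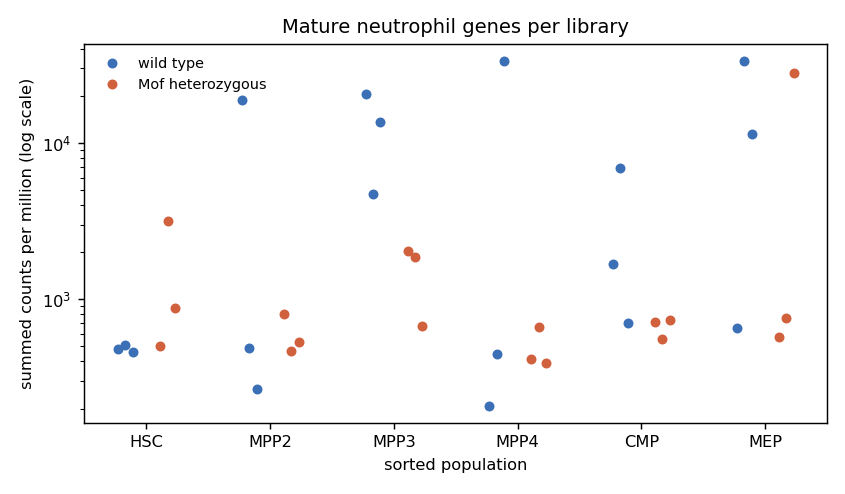
Summed CPM of the mature neutrophil genes in each library (log axis), by population and genotype. Wild-type MPP3 averages 12988 CPM against 1520 CPM in heterozygous MPP3, and single libraries stand out in wild-type MPP2, MPP4, CMP and MEP and in heterozygous MEP.

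Lymphoid priming genes (median -0.18, adjusted p = 0.00214; adjusted p = 0.293 with an estimated correlation) and G2/M genes (median -0.07, adjusted p = 2.73e-04; adjusted p = 0.661 with an estimated correlation) shifted lower relative to the other genes. Of the first, 12 of 18 were lower (Foxp1 -0.55, Bcl11a -0.02, Cd52 -0.07, Dntt 0.64), with 1 past the threshold when adjusted over the list alone and 0 over all genes. Of the second, 19 of 25 were lower, with 0 past it over the list alone or over all genes (Mki67 -0.75, Top2a -0.59, Ube2c -0.50, Cks2 0.03). Neither of the latter lists passed without the shallow libraries. The complexes in which Mof acts, MSL and NSL, did not differ as a list (median 0.13, adjusted p = 0.771, the test's direction being down; 0 of 11 members past the threshold over the list alone; Hcfc1 0.54, Msl3 0.46, Msl1 -0.35), nor did the other lysine acetyltransferases and deacetylases (median 0.12, adjusted p = 0.575). Among the surface proteins of the sort (median 0.09, adjusted p = 0.703), Cd34 (1.11, SE 0.29) and Kit (0.96, SE 0.33) passed when adjusted over the list alone, and 0 did over all genes. Flt3 differed by 0.61, Cd48 by 0.24, Fcgr3 by -0.06 and Ptprc by -0.41. Median differences of the other lists were 0.39 for megakaryocyte genes (adjusted p = 0.131), -0.01 for erythroid genes (0.105), 0.12 for myeloid genes (0.703), 0.27 for blood transcription factors (0.151), 0.15 for G1/S genes (0.805), 0.15 for quiescence genes (0.172), 0.05 for p53 targets (0.419), -0.02 for interferon response genes (0.716), 0.36 for glycolysis genes (0.139), 0.18 for respiratory chain genes (0.220) and 0.14 for ribosomal protein genes (0.556). The lists of T and NK cells (median -0.56, adjusted p = 0.419, 3 genes), mast cells (-0.07, 0.628), stroma (0.23, 0.704) and sex-linked genes (0.18, 0.790) did not pass, and no mitochondrially encoded gene was in the tables.

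In HSC, heterozygous libraries almost lacked the adult beta-globin transcript Beta-s. Beta-s (chromosome 7, 103826523 to 103827928) had 2181 counts in wild-type HSC, 202, 1197 and 782 per library, and 1 in heterozygous HSC, a 1724-fold lower level (309 to 68144). Its means were 487 ± 306 and 1.46 ± 2.53 normalised counts (SD, n = 3), and it fell by 7.84 log2 (SE 1.32, limma adjusted p = 0.00110). The count test gave -10.46 with an adjusted p = 0.189 (edgeR). Pooled over its libraries, wild-type HSC held 23019 CPM of Beta-s. The tested erythroid genes, which do not include Beta-s, summed to a mean of 4131 CPM in wild-type HSC. Whether the Beta-s reads came from the sorted cells was not tested. It was the 1 gene called by limma; 418 had an unadjusted p under 0.05, of which 6.46% were higher, and the count test called 0 (101 unadjusted). Limma called 10 genes without heterozygous HSC replicate 3 and 2 without wild-type HSC replicate 1.

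G2/M genes were lower in heterozygous HSC (median -1.14, camera adjusted p = 1.11e-06; adjusted p = 0.672 with an estimated correlation), 23 of 25 members, and 3 fell when adjusted over the list alone, against 0 over all genes: the proliferation marker Mki67 (-2.81, SE 0.75), the topoisomerase Top2a (-2.73, SE 0.84) and the ubiquitin-conjugating Ube2c (-2.16, SE 0.76). The erythroid list, in which Hba-a1 and Hbb-b2 were tested but Beta-s, under the tables' name, was not included, had a median of -0.99 (-1.08 with genes at 0 set to their bound; adjusted p = 8.02e-04; adjusted p = 0.672 with an estimated correlation), but adjusted p = 0.255 without wild-type HSC replicate 2 and 0.0752 without heterozygous HSC replicate 1. Ribosomal protein genes had a median of -1.29 (adjusted p = 3.59e-22; adjusted p = 0.672 with an estimated correlation), which was -0.03 (adjusted p = 0.715) without heterozygous HSC replicate 2, the shallowest library. Mature B cell genes (median -1.13, adjusted p = 0.0295) lost their call without wild-type replicate 3 (0.306) or heterozygous replicate 3 (0.5999), and mature neutrophil genes (median 0, mean 0.40, up, adjusted p = 0.0283) without wild-type replicate 2 (0.0545) or heterozygous replicate 2 (0.806); neither held with an estimated correlation. The median of all genes was -0.34 in HSC, and 0.02 without heterozygous HSC replicate 2, where 145 genes had an unadjusted p under 0.05. Over all libraries, 7.74% of genes had replicates of the genotypes that did not overlap, against 10% by chance.

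In MPP2, heterozygous libraries held more Apoe, the lipid carrier apolipoprotein E, and more F2r, the thrombin receptor PAR1. Apoe had 1 count in wild type and 90 in heterozygous libraries, a ratio of 30.4 (5.33 to 1216), and rose by 3.61 log2 (SE 0.70, limma adjusted p = 0.0114). F2r had 0 and 42 counts, at least 4.74-fold higher (floor of 3 counts over the group), and rose by 3.04 (SE 0.64, adjusted p = 0.0203). Exosc2 (0 against 32 counts, at least 3.61-fold; 2.91, SE 0.57, adjusted p = 0.0114), Erdr1 (1 against 58; ratio 19.6, 3.38 to 788; 3.19, SE 0.67, adjusted p = 0.0203) and the ribosomal pseudogene Rps15a-ps6 (3 against 72; ratio 8.12, 2.67 to 40.3; 3.08, SE 0.69, adjusted p = 0.0441) rose too. Apoe lies at 19696109 to 19699188 on chromosome 7, F2r at 95601803 to 95618487 on chromosome 13 and Rps15a-ps6 at 6172644 to 6173036 on chromosome 11 within Nudcd3.

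Limma called these 5 genes in MPP2, all higher, and the count test 18 (16 higher, 2 lower), including all 5; with RLE scaling it called 11 higher and 14 lower, and DESeq2 9 and 19. All wild-type MPP2 libraries are shallow, and leaving out a library left 0 genes (wild-type replicate 1 or 2, heterozygous replicate 1 or 2), 1 (heterozygous replicate 3) or 2 (wild-type replicate 3). The list of HSC genes rose (median 0.90, camera adjusted p = 0.00885; adjusted p = 0.563 with an estimated correlation; 3 over the list alone, with Ifitm3 2.25 and Ifitm1 2.01 among the members, and 0 over all genes), as did megakaryocyte genes (median 1.53, adjusted p = 0.00290; adjusted p = 0.498 with an estimated correlation; 0.0567 without heterozygous replicate 1) and ribosomal protein genes (median 0.76, 73 of 73 higher, adjusted p = 5.11e-08; adjusted p = 0.875 with an estimated correlation). Mature B cell genes (median -1.38, adjusted p = 1.45e-05; Vpreb3 -2.63), G2/M genes (-0.51, adjusted p = 7.86e-07) and lymphoid priming genes (-0.55, adjusted p = 0.00440; 0.0578 without wild-type replicate 3) were lower, each with adjusted p = 0.498 with an estimated correlation. Macrophage and dendritic cell genes (-1.47, adjusted p = 0.0148; adjusted p = 0.563 with an estimated correlation) lost their call without wild-type replicate 3 (0.494) or heterozygous replicate 3 (0.293). Mature neutrophil genes (median -1.34, or -2.06 with genes at 0 at their bound, adjusted p = 0.0473; adjusted p = 0.875 with an estimated correlation) lost it without wild-type replicate 1 (0.831), which held 18778 CPM of these genes, heterozygous replicate 1 (0.0692) or heterozygous replicate 3 (0.0839). The median of all genes was 0.21, and 0.37, 0.13 and 0.21 with TMM, RLE and total scaling.

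In MPP3, transcripts that rose in heterozygous libraries included Rgs1, a brake on chemokine receptor signalling (2 against 193 counts, ratio 14.2, 3.87 to 118), Lars2, the mitochondrial leucyl-tRNA synthetase (5 against 348, ratio 10.2, 4.34 to 31.7), Erdr1 (1 against 186, ratio 27.3, 4.85 to 1086), Ctla2a, a protease inhibitor (16 against 313, ratio 2.88, 1.74 to 5.09), and Gas5, a noncoding host of small nucleolar RNAs (13 against 243, ratio 2.75, 1.58 to 5.23). On the log2 scale they rose by 3.92 (SE 0.74, adjusted p = 0.00440), 3.87 (SE 0.90, adjusted p = 0.0339), 3.77 (adjusted p = 0.00179), 3.74 (SE 0.75, adjusted p = 0.00750) and 3.52 (SE 0.76, adjusted p = 0.0198) by limma. Rgs1 lies at 144242296 to 144249242 and Gas5 at 161034422 to 161038539 on chromosome 1, Lars2 at 123366927 to 123462666 on chromosome 9 and Ctla2a at 60934155 to 60936625 on chromosome 13. Limma called 20 genes, all higher, and 94.5% of the 1038 genes at an unadjusted p under 0.05 were higher, around a median of all genes of 0.56 (0.74, 0.47 and 0.49 with TMM, RLE and total scaling). The count test called 3 (186 unadjusted), which were Erdr1, Mir682 and Rpl31. Without the 6 shallow libraries, 1 wild-type MPP3 library was left against 3 heterozygous ones and was assumed to vary like the other groups. Limma then called 7 genes, of which 3 were among the 20. In that fit Erdr1 passed (4.44, adjusted p = 0.00103), and Rgs1 (2.77, adjusted p = 0.623), Lars2 (2.03, 0.842), Ctla2a (0.88, 0.849) and Gas5 (0.85, 0.842) did not. Leaving out 1 library gave 9, 7 and 403 genes for wild-type replicates 1, 2 and 3, and 6, 3 and 1 for heterozygous replicates 1, 2 and 3.

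The list of HSC genes rose in heterozygous MPP3 (median 1.78, 12 of 12 higher, camera adjusted p = 1.10e-06; adjusted p = 0.233 with an estimated correlation; 7 over the list alone and Rgs1 over all genes; Ifitm3 2.76, Ifitm1 2.58, Hlf 2.88). Immediate early genes (median 1.21, adjusted p = 0.0117; Nr4a1 3.24, Ier3 3.20) and ribosomal protein genes (median 1.17, adjusted p = 7.55e-09) rose too, each with adjusted p = 0.650 with an estimated correlation, and had adjusted p = 0.0911 and 0.349 with the 1 wild-type library that is not shallow. Quiescence genes (median 1.15) and glycolysis genes (1.07) passed at adjusted p = 0.0496 (adjusted p = 0.561 and 0.650 with an estimated correlation). Quiescence lost its call without wild-type replicate 2 (0.186) or 3 (0.213) or heterozygous replicate 1 (0.0582) or 2 (0.0899), and glycolysis without wild-type replicate 1 (0.111) or 2 (0.289) or heterozygous replicate 1 (0.0931) or 3 (0.0791). Mature neutrophil genes were lower (median -2.70, or -2.88 at the bound, adjusted p = 4.79e-13; adjusted p = 0.0867 with an estimated correlation; 7 fell and 1 rose over the list alone, 0 over all genes; S100a9 -4.02). The list summed to 12988 ± 7942 CPM in wild type and 1520 ± 740 in heterozygous MPP3. Relative to the other genes, myeloid genes (median -0.16, adjusted p = 3.82e-04; adjusted p = 0.360 with an estimated correlation) and G2/M genes (-0.37, adjusted p = 5.48e-07; adjusted p = 0.400 with an estimated correlation) were lower.

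Interferon response genes (median -0.09, mean 0.01, adjusted p = 0.0413), mature B cell genes (median 0.06, mean -0.07, adjusted p = 0.0413) and mast cell genes (median -0.27, adjusted p = 0.0465) also shifted lower in MPP3 against the other genes, with adjusted p = 0.413, 0.650 and 0.400 with an estimated correlation. The interferon call was lost without wild-type replicate 1 (0.0847) or 2 (0.250) or heterozygous replicate 2 (0.218). The B cell call was lost without wild-type replicate 1 (0.573) or 2 (0.328) or heterozygous replicate 2 (0.283), and the mast cell call without wild-type replicate 2 (0.262) or 3 (0.199) or heterozygous replicate 3 (0.104).

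In MPP4, counts of Erdr1 and of Mir682 rose. Mir682 is annotated as a microRNA gene within Gm4149 on the same strand, so its counts may belong to Gm4149. Erdr1 had 3 counts in wild type and 166 in heterozygous libraries (ratio 24.3, 8.16 to 119; 3.97 log2, SE 0.67, limma adjusted p = 0.00106), and Mir682 had 1 and 54 (ratio 23.7, 4.08 to 953; 2.78, SE 0.57, adjusted p = 0.0268). Limma and the count test each called these 2 genes. Erdr1 lost its call without wild-type MPP4 replicate 2 (adjusted p = 0.0686) or heterozygous replicate 1 (0.0732), and Mir682 without any library except wild-type replicate 3 (0.0687 to 0.240). Immediate early genes were lower (median -0.65, 16 of 18, camera adjusted p = 4.86e-04; adjusted p = 0.990 with an estimated correlation), as were mature neutrophil genes (median -1.68, or -4.56 at the bound, adjusted p = 0.00179; adjusted p = 0.990 with an estimated correlation), and G2/M genes were higher (median 0.83, 22 of 25, adjusted p = 0.0107; adjusted p = 0.990 with an estimated correlation). Without wild-type MPP4 replicate 3, which held 33370 CPM of neutrophil genes, none of the 3 lists passed (adjusted p = 0.0616, 0.892 and 0.612, the G2/M median becoming -0.12). The immediate early call was also lost without heterozygous replicate 1 (0.0703) and the G2/M call without heterozygous replicate 3 (0.852). The median of all genes was 0.17 on the deposited scale and 0.04 with RLE scaling.

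In CMP, immediate early genes, which code for transcription factors and stress proteins induced within minutes of a stimulus, were lower in heterozygous libraries. All 18 members were lower, with a median of -1.47 (camera adjusted p = 5.24e-23; adjusted p = 0.00571 with an estimated correlation), and 7 fell when adjusted over the list alone, against 1 over all genes. Klf6 had 93 counts in wild-type and 8 in heterozygous CMP, or 35.8 ± 14.6 against 2.15 ± 0.43 normalised counts (SD, n = 3), a 15.4-fold lower level (7.48 to 36.6), and fell by 3.48 log2 (SE 0.60, limma adjusted p = 0.00171; edgeR adjusted p = 1.98e-04). The AP-1 subunit Fos went from 800 ± 182 to 74.1 ± 64.9 CPM (167 against 24 counts; -3.80, SE 0.84), and Fosb (-2.85, SE 0.75), Jun (-1.98, SE 0.67), the zinc finger factor Egr1 (-2.14, SE 0.76), the phosphatase Dusp1 (-1.69, SE 0.69) and the chaperone Hspa1b (-2.15, SE 0.52) fell when adjusted over the list alone. Jund differed by -1.17. The other called gene, the sugar transporter Slc35b4 (chromosome 6, 34153380 to 34177111), rose (0 against 16 counts, at least 4.04-fold; 2.43, SE 0.51, adjusted p = 0.0465). It lies outside the naming rule and was chosen after its values were seen. Limma called 2 genes (240 unadjusted) and the count test 2, with Klf6 in both.

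Without wild-type CMP replicate 1 limma called 0 genes (Klf6 -3.18, adjusted p = 0.106), and without any other CMP library 1. The neutrophil list was lower in CMP (median -1.39, 10 of 10, adjusted p = 3.17e-04; adjusted p = 0.730 with an estimated correlation) but not without wild-type replicate 2 (0.635), whose summed level was 6945 CPM. The immediate early list passed in each of the 6 fits that left out 1 library (medians -1.69 to -1.32). Quiescence genes (median 0, mean -0.60, adjusted p = 0.00395; adjusted p = 0.478 with an estimated correlation) shifted lower, with Klf6 and Egr1, which are in both lists, past the threshold when adjusted over the list alone, and did not pass without wild-type replicate 2 (0.0518). Erythroid genes (median -0.36, or -0.40 at the bound, adjusted p = 0.0253; adjusted p = 0.969 with an estimated correlation) did not pass without wild-type replicate 1 (0.170) or 3 (0.0716) or heterozygous replicate 2 (0.106) or 3 (0.112).

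In MEP, heterozygous libraries held Cd34, the surface sialomucin that the gate for this population excludes, which was not counted in wild type. Cd34 had 16, 10 and 19 counts in the heterozygous libraries and 0 in the wild-type libraries, at least 12.1-fold higher, and rose by 3.71 log2 (SE 0.72, limma adjusted p = 0.0116; edgeR adjusted p = 0.00774). Gm10548, a processed pseudogene within Apc on chromosome 18 (34207775 to 34221772), fell by 2.85 (SE 0.56, adjusted p = 0.0116; 24 against 1 counts, 29.7-fold lower, 4.84 to 1220). Cd34 lies at 194938819 to 194961279 on chromosome 1 and overlaps Gm16897. Immediate early genes were lower here as well (median -1.10, or -1.22 at the bound, 15 of 18, camera adjusted p = 3.12e-09; adjusted p = 0.178 with an estimated correlation), and 4 fell when adjusted over the list alone, against 0 over all genes: Hspa1b (-2.40, SE 0.52), Klf6 (-2.20, SE 0.60), Ier5 (-2.33) and Fosb (-2.52). Fos differed by -1.54 (SE 0.84) and Jun by -1.54.

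**Figure D5:**
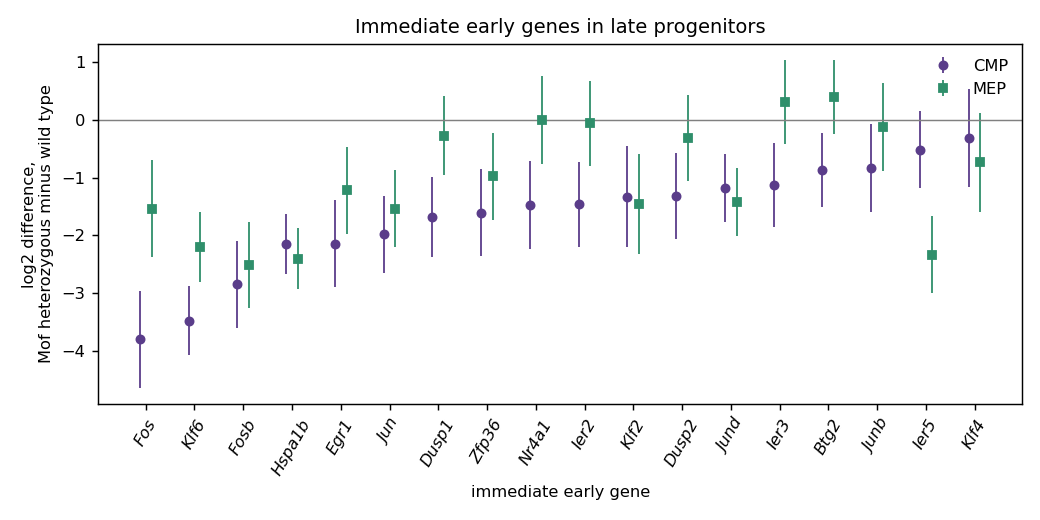
Log2 difference (heterozygous minus wild type, with SE) of the 18 tested immediate early genes in CMP (circles) and MEP (squares). All 18 lie below 0 in CMP and 15 in MEP.

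Mature B cell genes (median -1.70, or -1.89 at the bound, adjusted p = 2.68e-07; adjusted p = 0.178 with an estimated correlation) and mature neutrophil genes (median -1.66, or -1.74, adjusted p = 4.92e-05; adjusted p = 0.422 with an estimated correlation) were lower in heterozygous MEP, as were quiescence genes (median -0.32, adjusted p = 0.0109; adjusted p = 0.422 with an estimated correlation). Wild-type MEP replicate 2, which held 33261 CPM of neutrophil genes, decided these: without it the adjusted p was 0.0806, 0.999 and 0.512, and the immediate early median was -0.05 (adjusted p = 0.00455). Without heterozygous replicate 1 the neutrophil and quiescence lists did not pass either (0.0775 and 0.0554). Limma called 2 genes in MEP (340 unadjusted) and the count test 2, both higher, with Cd34 in both. Cd34 did not pass when any 1 library was left out (adjusted p = 0.0550 to 0.232), and Gm10548 passed without wild-type replicate 2 or heterozygous replicate 1 alone, with 0.0550 to 0.232 otherwise.

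The effect of genotype differed between populations for 2 genes. Counts of the first, Mir682, may belong to Gm4149, which overlaps it on the same strand. Mir682 (chromosome 13, 75645046 to 75645141, within Gm4149) was higher in heterozygous MPP2 (1.51), MPP3 (3.19; 0 against 69 counts, at least 3.38-fold) and MPP4 (2.78), and lower in HSC (-0.89, or -0.31 without the shallow HSC library), CMP (-0.70) and MEP (-1.40; 77 against 33 counts), with an interaction adjusted p = 1.91e-04 by limma. The gene Gm6251 (current symbol Rpl32l, annotated as protein coding, chromosome 10, 20208439 to 20209030, overlapping Map7) had values of similar sign (2.27, 2.43 and 1.37 in the MPP populations, -0.48 in HSC, -1.16 in CMP and -1.02 in MEP; adjusted p = 0.0485), but its HSC difference was 0.25 without the shallow HSC library. The 3 MPP populations, in which both genes were higher, share a pool in each genotype. The count test called 18 genes, and leaving out 1 library moved the limma count by over 1.5 times in 31 of 36 fits, to between 1 and 27 (without wild-type MPP3 replicate 3).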

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

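Of the tests in this part, the comparison of neutrophil RNA between libraries was chosen only after the result was seen.

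The genotype effect differed between populations for Mir682 (limma interaction adjusted p = 1.91e-04) and Gm6251 (adjusted p = 0.0485), which is why both stand here. Their log2 differences were 3.19 and 2.43 in MPP3 and -1.40 and -1.02 in MEP. Among 100 random assignments of genotype within populations, 28 gave as many genes as the 2 found, with up to 24, so chance cannot be excluded for the number of genes. The lines of the wild-type MEP table that stand where other tables hold spike-ins carried 7024 counts, and the named spike-ins of the 10 other tables that have them carried 60690 counts; the former were used in no comparison and the latter for counts per spike-in count alone.

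The first pattern is the one-sided effect in MPP3, where 20 genes rose and 0 fell while heterozygous libraries were deeper. When the heterozygous MPP3 libraries were thinned to the totals of the wild-type MPP3 libraries in 20 draws, the share of genes at an unadjusted p under 0.05 that were higher went from 94.5% to a median of 46.0% (37.9 to 55.1), and limma called a median of 0 genes (0 to 1; 198 unadjusted), with 0 of the 20. The median log2 difference of the 20 genes went from 2.88 to 1.57 (1.20 to 1.77), with 19 to 20 still higher. Depth may therefore account for the one-sidedness and for the number of calls. The 20 genes were picked as higher in these same libraries, so a remaining difference can come from that choice alone. Beyond it, genotype and pool cannot be told apart. The calls ended through lower depth as well as smaller differences.

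The second pattern is the lower level of immediate early genes in heterozygous CMP and MEP, with medians of -1.47 and -1.10, the latter -0.05 without wild-type MEP replicate 2, which held 33261 CPM of neutrophil genes. These genes are induced by handling and stress as well as by growth signals. A heat shock response that differed between the late progenitor pools would have moved heat shock genes with them, but the 15 tested ones had a median of -0.127 in CMP (quartiles -0.22 to 0.15) and -0.00331 in MEP; that list leaves out the inducible chaperone Hspa1b, counted as an immediate early gene, which was lower in both (-2.15 and -2.40), so a response of few genes stays open. A shift that scaling removes is argued against by the medians of the list under 3 scalings, of which the highest was -0.766. Genotype and pool, which includes any difference in the time from sort to freezing, cannot be told apart here because each genotype's CMP and MEP form 1 pool.

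The third pattern is the lower level of mature neutrophil genes, with an averaged median of -1.15. In 4 of the 6 wild-type populations the replicates differed by at least 5 times in the summed CPM of the list, and a low level in one replicate beside 33370 CPM in another is consistent with RNA of mature neutrophils, which lineage depletion and the gates should remove, in part of the wild-type libraries; S100a8 averaged 3578 CPM in wild-type MPP3. Heterozygous MEP replicates differed likewise, from 570 to 28120 CPM, so such RNA would not be limited to wild-type libraries. Depth as the whole cause is argued against: with libraries thinned to 7304 counts, the list's median was -1.48 (-1.72 to -1.28). An effect of genotype on the number of such cells or on these transcripts stays open and was not tested.

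For the averaged effect, random assignments of genotype within populations gave up to 10 genes. Of 100 assignments, the real one included, 2 gave as many as the real 5. That share is under 0.05, but 100 draws are too few to exclude chance assignment, and several other numbers were tested in the same way. Such assignments break the depth difference between the genotypes, and counts simulated at these depths gave 13 false calls (11 higher) for this contrast, so false calls from depth are not excluded. For gene lists chance assignment cannot be excluded either, since 28 of 100 gave as many as the real 7, with up to 10. Each single population has only 10 splits, too few for a share under 0.05. The real split gave 1 gene in HSC (3 of 10 splits as many, highest other 4), 5 in MPP2 (1 of 10, highest other 0), 20 in MPP3 (1 of 10, highest other 0), 2 in MPP4 (3 of 10, highest other 47), 2 in CMP (1 of 10, highest other 0) and 2 in MEP (2 of 10, highest other 11). For lists it gave 5 in HSC (9 of 10, highest other 13), 8 in MPP2 (4 of 10, highest other 8), 11 in MPP3 (1 of 10, highest other 7), 3 in MPP4 (10 of 10, highest other 8), 4 in CMP (2 of 10, highest other 4) and 4 in MEP (6 of 10, highest other 8). The splits with 47 genes in MPP4 and 11 in MEP point to a structure of the libraries other than genotype: both set wild-type replicate 1 with heterozygous replicates 1 and 2 against the rest, and in MEP the rest are the 3 libraries with the highest level of neutrophil genes.

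For the wild-type populations, 100 assignments, the real one included, gave as many genes in a share under 0.05 for the F test (245 genes, highest other 124, 1 as many). The same held for MPP3 (308, highest other 282, 1 as many) and MPP2 (79, highest other 446, 2 as many). These draws are too few to exclude chance, and simulation at these depths gave 256 false calls for MPP3 and 55 for MPP2. The share was larger for HSC (3, highest other 410, 24 as many), MPP4 (8, highest other 738, 12 as many), CMP (11, highest other 686, 8 as many) and MEP (5, highest other 789, 16 as many). Chance cannot be excluded for these either. Assignments that call 282 to 789 genes point to a structure of the libraries, such as depth, that gathers in 1 group by chance.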

How the results depend on the processing

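Chosen only after the results were seen were the edgeR test with TMM scaling, with and without the 6 shallow libraries, camera on recovered counts, the gene lists without shallow libraries, and the wild-type MEP names as deposited. The design had named edgeR with TMM scaling and camera on log2 CPM, but not their use on recovered counts. The averaged difference of Erdr1 kept its direction and call under all 12 alternatives (2.80 to 4.24), Klf6 under 10 of 12 (-1.73 to -1.13), Exosc2 under 9 of 12 (0.64 to 2.29) and E2f2 under 6 of 11. In CMP, Klf6 kept its call under 10 of 11 (-3.93 to -3.48), in MEP Cd34 under 11 of 12 (3.71 to 6.93), and in HSC Beta-s under 5 of 11. Depth limits HSC, MPP2 and MPP3 most, since 6 of their 18 libraries hold 12339 counts or fewer. No paired analysis was possible because the column numbers are running barcodes that no 2 groups share, so the fit with replicate number as a block and the limma-voom fit with it as a random effect were not run. The MPP2 comparisons could not be fitted without the shallow libraries, whose other fits average over 5 populations and hold 1 wild-type MPP3 library, assumed to vary like the other groups, and Kat8 has no value under the stricter filter. Where no reason is given below, the cause was not tested.

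Numbers of called genes moved as follows. DESeq2 called 53 genes on average, 2 in HSC, 28 in MPP2, 0 in MPP3 (237 unadjusted), 33 for the interaction, and 2, 40, 96 and 108 for wild-type MPP3, MPP4, CMP and MEP. edgeR with RLE scaling called 25 on average, 0 in HSC (91 unadjusted), 25 in MPP2, 2 in MPP3, 14 for the interaction, and 36, 4, 30, 81 and 80 for wild-type MPP2, MPP3, MPP4, CMP and MEP. edgeR with total scaling called 38 on average, 0 in HSC (94 unadjusted), 22 in MPP2, 0 in MPP3 (150 unadjusted), 18 for the interaction, and 29, 4, 20, 92 and 100 for wild-type MPP2, MPP3, MPP4, CMP and MEP. edgeR with TMM scaling called 31 on average, 0 in HSC (101 unadjusted), 18 in MPP2, 3 in MPP3, 18 for the interaction, and 10, 4, 1, 22, 87 and 113 for wild-type HSC, MPP2, MPP3, MPP4, CMP and MEP. Without the shallow libraries that test called 2 on average, 0 in HSC (191 unadjusted), 0 in MPP3 (202 unadjusted), 10 in MPP4, 5 in CMP and 12 for the interaction.

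Among limma fits, no filter gave 2 genes in HSC, 1 in MPP2, 7 in MPP3, 9 in MPP4, 32 in CMP, 53 in MEP, 29 for the interaction, and 72, 50, 166, 20 and 45 for wild-type HSC, MPP2, MPP3, MPP4 and MEP. The stricter filter, which tests fewer genes (1095), gave 8 on average, 14 in MPP2, 75 in MPP3, 1 in CMP, 1 in MEP, 9 for the interaction, and 0 (40 unadjusted), 32, 131, 2 and 7 for wild-type HSC, MPP2, MPP3, MPP4 and CMP, with 22 list calls against 42. With the 2 tables of 1 population alone, which leaves fewer libraries for the spread, 0 genes passed in HSC, MPP2, MPP3 and MPP4 (158, 706, 1360 and 315 unadjusted). Leaving out the shallow libraries gave 2 on average, 7 in MPP3, 33 in MPP4, 5 in CMP, 6 in MEP, 20 for the interaction, 51, 55, 169 and 30 for wild-type HSC, MPP3, MPP4 and MEP, and 25 list calls. A pseudocount of 0.1 gave 16 in MPP2, 235 in MPP3, 0 in MPP4 (436 unadjusted), 0 in CMP (91 unadjusted), 0 in MEP (174 unadjusted), 1 for the interaction, and 0 (437 unadjusted), 235, 796, 1 and 5 for wild-type HSC, MPP2, MPP3, MPP4 and CMP; the Kat8 difference then reversed to 0.0158. Leaving out ribosomal and sex-linked genes gave 5 for wild-type HSC, and sums over replicates gave 1 on average. With the wild-type MEP names as deposited, 1654 genes passed on average, 3534 in MEP, 2414 for the interaction, and 241, 447, 594, 230, 333 and 2142 for wild-type HSC, MPP2, MPP3, MPP4, CMP and MEP, because names and values of that table are then shifted against each other. Of 42 list calls, 1 held with an estimated correlation, fry made 3 and camera on recovered counts 52.

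Leaving out 1 library at a time gave 4 to 43 genes on average (43 without heterozygous HSC replicate 2), 1 to 10 in HSC, 0 to 2 in MPP2, 1 to 403 in MPP3 (403 without wild-type replicate 3), 0 to 2 in MPP4, 0 to 1 in CMP, 0 to 2 in MEP and 1 to 27 for the interaction. For wild-type populations it gave 0 to 9 in HSC, 23 to 188 in MPP2, 4 to 987 in MPP3, 1 to 12 in MPP4, 2 to 14 in CMP and 5 to 8 in MEP. List calls ran from 37 to 50. The Kat8 difference ran from -0.16 to 0.0502, positive without wild-type CMP replicate 2, and its p across wild-type populations from 0.256 to 0.715 (limma F test). Erdr1 (2.64 to 2.94), Exosc2 (1.06 to 1.28) and Klf6 (-1.51 to -1.30) passed in all 36 such fits on average, and E2f2 (-1.52 to -1.20) in 10. Beta-s passed in all 6 in HSC (-8.65 to -7.39).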

Other observations

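Chosen only after the result was seen were the test of counts per spike-in count, with and without the shallow HSC library, and the test of genes near Kat8, with and without Tspan32 and Ifitm1.

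In this and the next paragraph each wild-type population is set against the mean of the other 5. Erythroid genes (median 0.49 log2, camera adjusted p = 0.0449; adjusted p = 0.858 with an estimated correlation) and megakaryocyte genes (0.87, adjusted p = 0.0334; adjusted p = 0.461 with an estimated correlation) were higher in HSC than in that mean, while G1/S genes (-0.51, adjusted p = 3.80e-05; adjusted p = 0.461 with an estimated correlation) and mast cell genes (2 genes tested; -1.10, adjusted p = 0.0334; adjusted p = 0.0856 with an estimated correlation) were lower. HSC were not at the extreme for any of these: summed CPM were higher in MEP for erythroid genes (5381 against 4131) and in CMP for megakaryocyte genes (1393 against 1249.9). They were lower in MPP3 for G1/S genes (2541 against 2738) and in MPP2 for mast cell genes (0 against 11.5). In wild-type MPP2, G2/M genes were higher (0.58, adjusted p = 1.79e-04; adjusted p = 0.837 with an estimated correlation), and in wild-type CMP they were lower (-0.72, adjusted p = 8.03e-10; adjusted p = 0.113 with an estimated correlation).

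Wild-type CMP also held more of the mast cell, basophil and eosinophil list (2 of its 15 genes tested; median 2.03, adjusted p = 6.37e-04; adjusted p = 0.00799 with an estimated correlation) and of megakaryocyte genes (1.03, adjusted p = 0.00160; adjusted p = 0.192 with an estimated correlation), and less of lymphoid priming genes (-0.50, adjusted p = 1.01e-05; adjusted p = 0.0836 with an estimated correlation). Wild-type MEP held more of respiratory chain genes (0.67, camera adjusted p = 6.10e-05; adjusted p = 0.522 with an estimated correlation) and of ribosomal protein genes (0.62, adjusted p = 1.17e-08; adjusted p = 0.549 with an estimated correlation; 189015 summed CPM, below the 194077 of CMP), and less of immediate early genes (-0.84, adjusted p = 6.28e-08; adjusted p = 0.0636 with an estimated correlation).

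Tspan32 and Ifitm1, both higher in heterozygous libraries, lie on chromosome 7 as Kat8 does. A candidate explanation is variants of another strain carried along with the Mof allele. Of 149 tested genes within 20 Mb of Kat8, 24 (16.1%) had an unadjusted averaged p under 0.05, against 10.6% of all placed genes, and 4.84% of 3163 windows of as many neighbouring genes held as many. These 24 include the genes that prompted the test. With Tspan32 and Ifitm1 left out, 22 of 147 genes (15.0%) had such a p, and 12.5% of 3201 windows held as many. The explanation is left open, and strains are not given in the labels.

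Erdr1, placed near the end of the sex chromosomes, was higher in heterozygous libraries of all 6 populations. Animals of different sex in the genotypes would move Xist and Y-linked genes apart. They did so in 0 of 6 populations: Xist had 1 count in wild-type and 1 in heterozygous MPP3 and 0 elsewhere, and Y-linked genes had counts in every group, 54 in wild-type and 54 in heterozygous MEP. Sex as the source of the Erdr1 difference is argued against.

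A difference in RNA per cell between the genotypes was not detectable from the spike-ins. Counts per spike-in count differed by a mean of 0.185 log2 over the 5 populations with spike-ins in both genotypes (two-sided exact permutation p = 0.556, 3200000 permutations within populations, 30 libraries). The mean rests on HSC (0.93), where heterozygous replicate 2 had 13 spike-in counts. Without that library HSC differed by -0.02 and the mean was -0.00325 (exact permutation p = 0.99, 1600000 permutations, 29 libraries), so the hypothesis of fewer transcripts in heterozygous cells is left open.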
